A study of Mus musculus with 2 samples.

How the data were processed

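DNase-seq was done on heart tissue of 2 female B6CASTF1/J mice at an age of 10 days, 1 library per animal, with the labels naming them as biological replicates 1 and 2 of separate donor animals. For each library the deposited processed data comprise 2 peak lists, a list of footprints and a list of bases with the FDR of their cut rate, on the mm10 build per the labels. Per the file headers, which list what each file was derived from, peaks and FDR values came from the filtered alignments of that library alone, and footprints from its FDR values and alignments, so calls were made per library and never on pooled animals. The aligner, the peak caller and their settings are not given in the sources used here.

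The deposited value of each peak is a signal, a density within the library that is never below 0. In the longer lists all values below 2 were whole multiples of 1 step per library within a tolerance of 0.02 steps, a step of 0.00558 in replicate 1 and 0.00646 in replicate 2. The scale is not stated, so depth is unknown. Peak values are the authors' own and were used to describe, rank or filter peaks within a library and to correlate shared peaks. Averaged over both libraries, they were used to rank genes and peaks for naming and to describe or filter reproducible peaks. The averages also served to compare X-linked with autosomal promoters and sets of X-linked genes with each other. The deposited FDR cut rate is a q-value (p-value adjusted for the many bases tested) from 0 to 0.05 per stretch of bases. The footprints carry a constant deposited p-value level of 0.01. The design written before the data were examined named peaks and hotspots, and the files hold 2 peak lists instead. Every peak of the shorter lists (115986 and 110640 peaks) held a base with an FDR under 0.001, and every peak of the longer lists (177762 and 172334) held one under 0.05. The shorter lists were taken as the main peaks before any result was computed, and the longer lists as an added alternative in the place of hotspots.

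Coordinates were compared with the GRCm38 reference sequence, the same build, and all deposited ends lay inside its 21 chromosomes. Genes and start sites came from the GENCODE M21 basic annotation. Printed coordinates count from 1. A reproducible peak is a replicate 1 peak that overlaps a replicate 2 peak by at least 1 bp, and its value is the mean of its own value and that of the strongest overlapping replicate 2 peak. Promoters were within 1000 bp of the TSS of a protein-coding transcript, and distal peaks lay more than 1000 bp from any annotated TSS. The promoter value of a gene in a library was that of its strongest peak over all its protein-coding start sites. Chance overlap came from 10 shuffles within chromosomes, and chance location from 3. Shares of reproducible peaks are over 87545 peaks, a single set that both libraries define, so they carry no spread between animals.

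The 20 gene lists hold 326 entries, all found in the annotation, and were written before the data were examined with the 25 consensus sequences. The number of list members with a reproducible promoter peak was compared with 10000 random lists of other genes matched in 20 bins of promoter CpG number. The median number of distal peaks per locus (gene body and 50 kb to either side) was compared with 10000 random lists matched in 20 bins of gene length. Both gave two-sided empirical p-values, of which the smallest possible is 0.0002, with Benjamini-Hochberg adjustment over the lists and a threshold of 0.05. Consensus matches on either strand were counted in the central 150 bp of distal reproducible peaks and in windows 1000 bp to the left and right. The test was an exact binomial test of peaks with a match in the centre or in 1 randomly chosen flank but not both, adjusted over the motifs. A match counted as footprinted when footprints covered at least 50% of it. Copies of peak sequences were searched with blastn 2.17.0 in the reference chromosomes at 90% identity over 80% of the peak.

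Genes were named by a rule set beforehand: in each list the 3 members with the highest mean promoter value, up to 3 members with no promoter peak in either library, and the 2 with the most distal peaks, besides the 10 protein-coding genes with the most distal peaks and the 10 strongest distal reproducible peaks. Not every gene the rule allows is given a sentence, and Srf and Tbx20 were named after their values were seen. Means over both libraries weigh replicate 2 more, since its values are higher.

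The tests were run on simulated data first. Each self-test of lists used 20 lists and 2000 random lists per list. For promoter lists of 18 genes among 21827, with planted lists drawn from the 12 lowest of the 20 CpG bins, where an increase has room to show, raising the odds of a peak 6-fold was called in 2 of 4 lists and 30-fold in 4 of 4. For distal counts a factor of 2 was called in 1 of 4 lists and a factor of 3 in 3 of 4. No unchanged list of 12 was called in either test. Of 5 motifs planted in 8% of 5000 simulated peaks, 5 were called, and of the 20 other motifs 0. With lists of this size, moderate differences can be missed. A first form of the promoter self-test, with smaller planted differences and more unchanged lists, called none of the planted lists, and it was replaced by this one after that was seen.

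Alternatives were promoter windows of 500 and 2500 bp, loci of 20 and 100 kb, central windows of 100 and 200 bp, flanks at 500 and 2000 bp, the peaks of each library alone, the stronger 50% of peaks, a reciprocal overlap of 0.5, the 50000 strongest peaks, autosomes only, random lists without CpG matching or matched on TSS number too, and promoter peaks for the motifs. The longer lists and the motif test without repeat-masked windows were added after the data were seen. Tests of the gene lists' peak values between the libraries were also run, passed the threshold for no list, and were removed because the scale of the values is not stated. The difference between libraries at motif sites was first seen as a ratio of values and then recomputed as ranks within each library. Scripts used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pysam 0.24.0 and matplotlib 3.10.9. Strain variants of the CAST parent and allele-specific signal were not analysed here.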

Results

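DNase-seq maps open chromatin by cutting nuclei with the nuclease DNase I and sequencing the cut ends, since bound nucleosomes protect most DNA. Here it was applied to heart tissue from female B6CASTF1/J mice, the first-generation cross of C57BL/6J with the wild-derived CAST strain, on postnatal day 10. There was 1 group of 2 animals with 1 library each, called replicate 1 and replicate 2, and no second group, so the comparisons are between the animals, between regions of the genome and between gene lists. The deposited values have no stated depth. Bases passing the authors' false discovery rate (FDR) of 0.05 spanned 64.4 Mb in replicate 1 and 52.8 Mb in replicate 2, and those passing 0.001 spanned 40.6 and 34.2 Mb. Stretches at or under 0.001 made up 73.2% and 76.3% of the listed stretches, and those at or under 0.01 made up 86.5% and 87.9%.

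The 2 hearts shared most of their accessible sites, and the strong ones nearly without exception. Replicate 1 had 115986 peaks with a median width of 200 bp that covered 24.5 Mb, and replicate 2 had 110640 peaks with a median width of 180 bp that covered 20.4 Mb, a mean of 113313 ± 3780 peaks (SD, n = 2). Of the replicate 1 peaks, 87545 (75.5%) overlapped a replicate 2 peak by at least 1 bp, against 1.77% after their positions were shuffled within chromosomes. Of the replicate 2 peaks, 88565 (80.05%) overlapped a replicate 1 peak. Among the strongest 10% of peaks, 99.7% of those in replicate 1 and 99.5% of those in replicate 2 were shared, against 31.7% and 47.7% in the weakest 10%. Of the peaks found in 1 heart only, 62.7% of the 28441 unshared replicate 1 peaks held a base at an FDR of 0.05 or less in replicate 2, and 72.8% of the 22075 unshared replicate 2 peaks held one in replicate 1. At an FDR of 0.001, which every peak meets in its own library, the shares were 10.1% and 24.4%. Across the 87545 shared peaks, the log2 of the authors' peak value correlated with a Pearson r of 0.909 and a Spearman rho of 0.887. This correlation is across peaks, which are not independent replicates, and carries no p-value. The replicate 2 values were a median of 1.55-fold the replicate 1 values, with 12.1% of peaks over 2-fold away from that median, and the median is not read as a difference between hearts because the scale of the values is not stated.

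**Figure D1:**
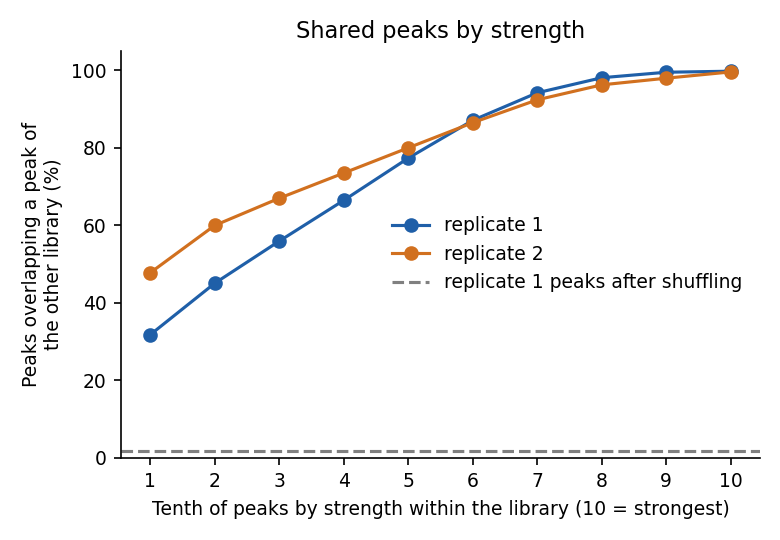
Percent of each library's peaks that overlap a peak of the other library (y axis), in 10 bins of peak strength within the library (x axis, bin 10 is strongest), for replicate 1 (blue) and replicate 2 (orange), with the share of replicate 1 peaks after shuffling (dashed). The share rises from 31.7% and 47.7% in the weakest bin to 99.7% and 99.5% in the strongest, against 1.77% after shuffling.

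Peaks of replicate 1 that overlapped a replicate 2 peak are called reproducible below. They lay at promoters far more often than randomly placed peaks did, yet most were far from any start site. Within 1000 bp of a protein-coding transcription start site (TSS) lay 25.7% of the 87545 reproducible peaks, against 2.45% of randomly placed ones. Exons held 3.70% (2.498% at random), introns 34.8% (37.2%) and intergenic sequence 35.9% (57.8%). Promoter peaks were stronger, with a median value of 3.35 against 1.27 in introns and 1.22 between genes. In all, 61519 peaks (70.3%) lay more than 1000 bp from every annotated TSS and are called distal. Of 21827 protein-coding genes, 14122 (64.7%) had a reproducible promoter peak, and the share rose with promoter CpG content, from 1.88% of genes in the lowest 10% to 96.1% in the highest.

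Promoters of the genes that build and fuel heart muscle were open well above the level of random genes with the same CpG content, and so were promoters of the other main cell types of the heart. Of 22 cardiomyocyte contractile genes, which encode the sarcomere and its Z-discs, 21 had a reproducible promoter peak, against 9.92 expected from 10000 random lists matched on CpG content (adjusted p = 0.001, n = 22 genes). The strongest, here and below by the mean of both libraries, were Myl4, the atrial essential light chain (mm10 chromosome 11, 104550663 to 104595753), with promoter peak values of 14.0 in replicate 1 and 26.4 in replicate 2, Tpm1, a tropomyosin (10.99 and 21.4), and Cryab, a small heat shock protein (6.04 and 9.75). All 20 genes of fatty acid and oxidative metabolism had a peak, against 14.2 expected (adjusted p = 0.001, n = 20 genes). They were led by the nuclear receptor gene Esrra (18.4 and 33.8), Acadm, an enzyme of fatty acid oxidation (10.97 and 22.6), and the fatty acid sensor Ppara (8.61 and 19.0). Calcium handling and channel genes had 18 of 20, against 14.9 expected (adjusted p = 0.0349, n = 20 genes). Among them Atp2a2, the calcium pump of the sarcoplasmic reticulum (5.54 and 12.9), the potassium channel gene Kcnj2 (6.90 and 11.5) and the connexin gene Gja5 (5.52 and 12.3) were strongest, and Sln, which encodes sarcolipin, an atrial inhibitor of that pump, had no promoter peak in either library. With a window of 2500 bp all 20 genes of this list had a peak, Sln included. Promoter values are the strongest over all annotated protein-coding start sites of a gene. Which site carried the value was not examined, a limit for long gene models such as Gja5 (mm10 chromosome 3, 96904693 to 97077416) and Myl4.

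Of the other heart cell types, all 15 fibroblast genes had a promoter peak, against 8.999 expected (adjusted p = 0.001, n = 15 genes), with Fn1 (6.62 and 13.1), Pdgfra (4.81 and 10.9) and Col1a1 (4.97 and 10.4) strongest. Endothelial genes had 18 of 20, against 13.1 expected (adjusted p = 0.0211, n = 20 genes), led by the transcription factor gene Ets1 (10.4 and 21.1) and by Eng (2.73 and 6.07) and Esam (2.46 and 4.47). Smooth muscle and pericyte genes had 14 of 15, against 9.71 expected (adjusted p = 0.03, n = 15 genes), led by Smtn (7.33 and 10.1), Des (4.39 and 7.87) and Myh11 (2.36 and 7.30), while Mylk had none in either library. With a window of 2500 bp all 15 genes of this list had a peak, Mylk included. The call for calcium handling genes ended with a promoter window of 500 bp (adjusted p = 0.165, n = 20 genes), without replicate 2 (0.0656) and with the stronger peaks alone (0.492). The endothelial call ended with a window of 2500 bp (0.082) and with the stronger peaks alone (0.412), and the smooth muscle call with a window of 500 bp (0.0633), with the stronger peaks alone (0.178) and with the longer peak lists (0.0784).

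Genes of body position, the germ line, the epicardium, leukocytes and epithelia had fewer open promoters than CpG-matched genes. In the Hox A and C clusters, which mark position along the body axis, 6 of 19 genes had a reproducible promoter peak, against 17.6 expected (adjusted p = 0.001, n = 19 genes). These genes are neighbours within their clusters, whereas the random genes came from the whole genome. They are not independent of each other, so this p-value can be too small. The strongest were Hoxa10 (1.59 and 5.03) and Hoxa4 (1.78 and 3.70), and Hoxa2, Hoxa3 and Hoxa7 had none in either library. Germ line genes had 2 of 12, against 7.48 expected (adjusted p = 0.002, n = 12 genes). One of them was Dazl, which encodes an RNA-binding protein of germ cells, with values of 4.72 and 10.2, and the other was Nobox (0.624 and 0.659), while Ddx4, Sycp1 and Sycp3 had none. Epicardial genes had 3 of 10, against 7.25 expected (adjusted p = 0.002, n = 10 genes): Tbx18 (4.68 and 7.11), Aldh1a2 (2.12 and 5.94) and Wt1 (1.43 and 2.11) had a peak, while Upk3b, Msln and Krt8 had none. Epithelial genes had 6 of 13, against 9.69 expected (adjusted p = 0.03, n = 13 genes), led by Krt10 (5.15 and 10.1), Elf3 (1.87 and 6.14) and Cdh1 (0.446 and 0.801), with no peak at Krt5, Krt14 or Krt1. Macrophage and leukocyte genes had 1 of 15, against 5.17 expected (adjusted p = 0.03, n = 15 genes). Cd68 (0.926 and 1.32) and Cd14 (0.602 and 0.807) had a promoter peak in each library, Lyz2 had one in replicate 1 only (0.636), and Ptprc, Csf1r and Spi1 had none. Both libraries still held listed bases near the start sites of Csf1r (lowest FDR 0.00861 and 0.00833) and Spi1 (0.00789 and 0.00322). In the longer lists 8 of the 15 genes had a promoter peak, against 6.08 expected. The count of 1 of 15 rested on replicate 2: the peaks of replicate 1 alone reached 6 of the 15 genes, against 5.58 expected (adjusted p = 1, n = 15 genes), and those of replicate 2 alone reached 2, against 5.61 (adjusted p = 0.0743). The epicardial call ended without CpG matching (adjusted p = 0.067, n = 10 genes) and with the longer lists (0.962), the epithelial one with a window of 2500 bp (0.082), without replicate 1 (0.0743), without CpG matching (0.294) and with the longer lists (0.0698), the germ line one with a window of 2500 bp (0.0942), and the leukocyte one also with a window of 500 bp (0.0502) and with the longer lists (0.507).

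The other 9 lists did not pass the test, and in 4 of them nearly all members and nearly all CpG-matched genes had a peak. Housekeeping genes had 18 of 18 (16.7 expected), circadian clock and nuclear receptor genes 18 of 18 (16.8), cell cycle genes 21 of 21 (19.7) and cardiac transcription factors 19 of 20 (18.5), with adjusted p of 0.587, 0.587, 0.587 and 1. Hand1, a transcription factor gene of the early heart, was the cardiac factor with no promoter peak in either library, whereas Hey2 (11.4 and 27.9), Tead1 (7.84 and 25.2) and Mef2a (9.32 and 17.8) were strongest by the mean of both libraries, although in replicate 1 Srf (9.97) exceeded Mef2a and Tead1, and Tbx20 (8.05) exceeded Tead1. Among cell cycle genes Ccne1 (12.7 and 32.3), Mcm5 (15.7 and 24.2) and Ccna2 (11.6 and 22.4) led. The strongest promoter of the clock list was that of Tef (15.7 and 38.0), a clock output factor, followed by Nr1d2 (14.0 and 22.4) and Nr1d1 (14.6 and 21.3), and that of the housekeeping list was Rplp0 (19.1 and 32.2), followed by Eef2 (12.2 and 32.4) and Psmb2 (10.6 and 29.1). Fetal and perinatal muscle isoforms had 7 of 10 (5.12 expected, adjusted p = 0.431, n = 10 genes), including Actn1 (5.63 and 7.21) and the natriuretic peptide gene Nppb (2.04 and 4.22). Schwann cell and neuron genes had 8 of 13 (9.12 expected, adjusted p = 0.587, n = 13 genes). The synaptic gene Snap25 had values of 2.68 and 8.41, with no peak at Sox10 or Th. Skeletal muscle genes had 7 of 17 (9.71 expected, adjusted p = 0.278, n = 17 genes): Actn3 (7.61 and 15.6) and Mylpf (6.32 and 15.96) were strongest, and the myogenic factor genes Myf5, Myog and Myf6 had no promoter peak. Liver genes had 3 of 17 (5.89 expected, adjusted p = 0.16, n = 17 genes), namely Apob (0.981 and 3.72), Foxa1 (1.13 and 2.80) and Apoa2 (0.742 and 1.58), and Alb, Apoa1 and Apoc3 had none. Erythroid genes had 2 of 11 (3.48 expected, adjusted p = 0.587, n = 11 genes), among them Tal1 (1.41 and 1.82), with no promoter peak at the globin genes Hbb-bt, Hbb-bs and Hba-a1. Under other settings some of these lists did pass: with a window of 500 bp liver (0 of 17, 5.49 expected) and skeletal muscle genes (4 of 17, 9.23 expected) were lower, with the stronger peaks alone Schwann cell and neuron genes were lower (3 of 13, 8.04 expected), and without replicate 1 fetal isoforms were higher (10 of 10, 5.45 expected), with adjusted p of 0.000667, 0.008, 0.00333 and 0.004. Without CpG matching cardiac transcription factors, cell cycle, housekeeping and clock genes were higher and erythroid and liver genes lower, with adjusted p of 0.00727 or less. These p-values, two-sided and Benjamini-Hochberg adjusted over the 20 lists, describe the 2 libraries, since genes are not replicates.

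**Figure D2:**
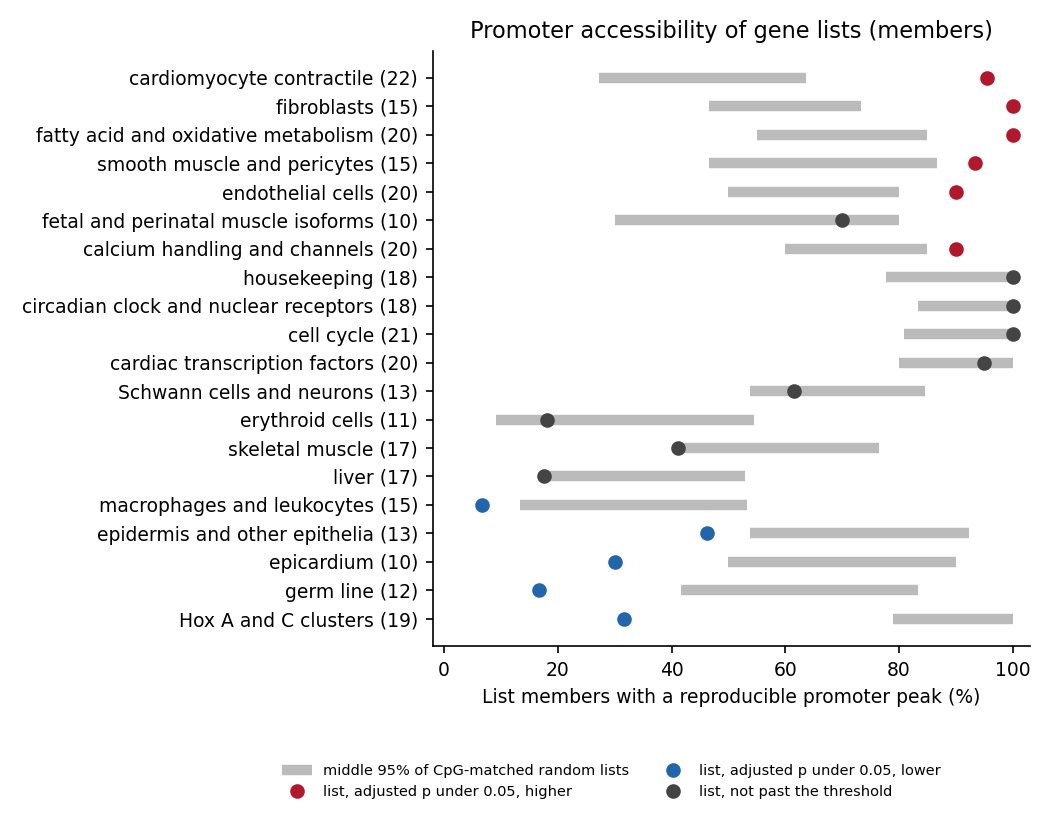
Percent of each gene list's members with a reproducible peak within 1000 bp of a protein-coding TSS (points, number of members in parentheses) against the middle 95% of 10000 CpG-matched random lists (grey bars). Contractile genes (21 of 22) and fibroblast genes (15 of 15) lie furthest above their range, and the Hox A and C clusters (6 of 19) furthest below.

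Distal sites were concentrated around contractile genes, cardiac transcription factors and the circadian and nuclear receptor genes. Contractile genes had a median of 8 distal reproducible peaks in the gene body or within 50 kb, against 4.06 for random lists matched on gene length (adjusted p = 0.03, n = 22 genes). Myl2, the ventricular regulatory light chain, had 29 and Tnnt2, cardiac troponin T, had 22. Cardiac transcription factors had a median of 9, against 4.86 (adjusted p = 0.048, n = 20 genes), with 38 at Prdm16 and 26 at Tead1. Circadian and nuclear receptor genes had a median of 10.5, against 5.25 (adjusted p = 0.028, n = 18 genes), with 50 at Rora and 43 at the thyroid hormone receptor gene Thra. The loci of Thra and Nr1d1 (38 peaks) overlap, so some peaks counted for both genes. The other 17 lists did not pass the test at these settings. Their medians ran from 2 for the Hox clusters (3.29 expected, adjusted p = 0.784, n = 19 genes) to 9.5 for calcium handling genes (6.51 expected, adjusted p = 0.229). With loci widened to 100 kb none of the 3 lists passed (adjusted p = 0.063 for contractile genes, n = 22 genes, 0.571 for transcription factors and 0.063 for clock genes). The call for transcription factors also ended with the stronger peaks alone (0.0528), and that for clock genes without replicate 1 (0.093). Calls were gained by endothelial (adjusted p of 0.021) and cell cycle genes (0.0328) with 20 kb loci, by calcium handling genes without replicate 2 (0.036), and in the longer lists by endothelial (0.00933), cell cycle (0.028), fetal isoform (0.042), smooth muscle (0.032) and housekeeping genes (0.0312).

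The protein-coding genes with most distal peaks were long. Gm20388 (350 peaks over a gene model of 4435 kb), Fgfr2 (134 over 2961 kb) and Gm37240 (64 over 1391 kb) have annotated transcripts that run across neighbouring genes. Gse1 had 76, Nav2 65, Tns1 59, Kalrn 55, Camta1 54, Cdh13 52 and Rora 50. By fixed 50 kb windows, which do not depend on gene length, the densest stretch was mm10 chromosome 11, 98750001 to 98800000, with 31 reproducible peaks over the 3' part of Thra, the clock repressor gene Nr1d1 and the start of Msl1. Peaks of 1 library can overlap each other and were counted separately, here and per gene. In this window the replicate 1 peak at 98751141 to 98751460 lay inside that at 98751141 to 98751760. Likewise, that at 98765721 to 98765920 lay inside that at 98765561 to 98766180, and that at 98777161 to 98777420 inside that at 98776881 to 98777520. By distinct sites the rank of this window over the next, with 30, could differ. With 20 kb windows a stretch of Bahcc1 ranked first (25 peaks) and one of Thra 7th (16). Within the 50 kb window the strongest peaks lay in Nr1d1 at 98773821 to 98774180 (value 14.1 in replicate 1, 26.1 for its counterpart in replicate 2) and at its upstream end at 98775281 to 98775540 (14.6 and 21.3). A window on chromosome 10 (81400001 to 81450000) held 30 over Nfic, and a window on chromosome 11 (120200001 to 120250000) held 29 over Bahcc1. The window with Aurkb and the clock gene Per1 (chromosome 11, 69050001 to 69100000) held 26. The window of Hand2, a transcription factor gene needed for the right ventricle (chromosome 8, 57300001 to 57350000), held 23, and that of Myl2 (chromosome 5, 122100001 to 122150000) held 21.

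**Figure D3:**
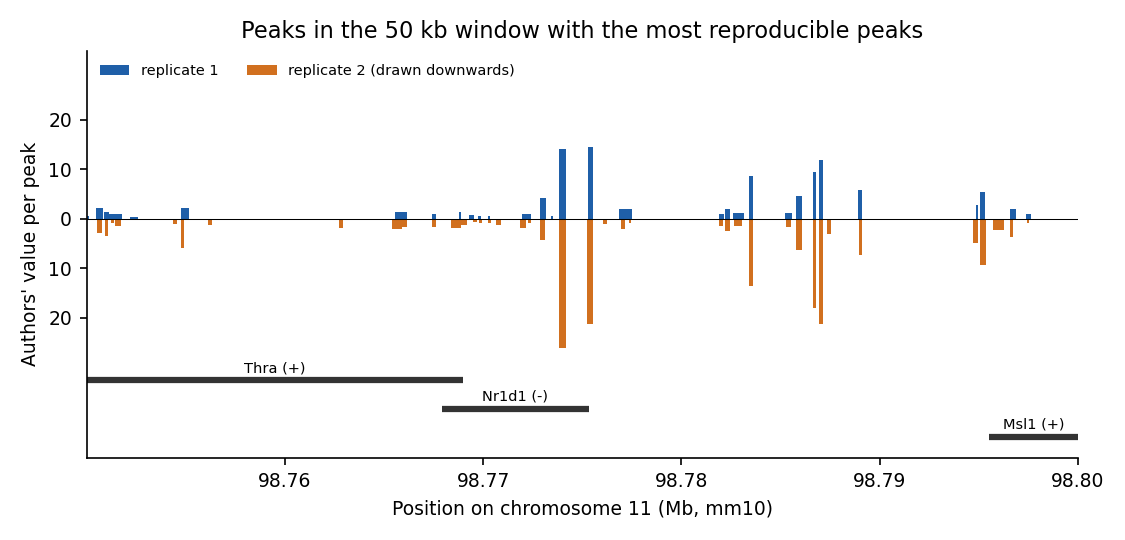
Peaks in mm10 chromosome 11, 98750001 to 98800000 (x axis, Mb), with the authors' value per peak for replicate 1 drawn upwards and for replicate 2 downwards, and gene spans below with their strand. The window holds 31 reproducible peaks, with overlapping ones counted separately. The strongest lie in Nr1d1 and at its upstream end.

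The 10 strongest distal reproducible peaks included sequence present in several copies. By the mean of both libraries the strongest lay inside Mid1 (chromosome X, 169998241 to 169998420), with values of 21.9 and 106, a rank that rested on replicate 2 since 5 of the other 9 had higher values in replicate 1, next to a second peak in the same gene at 169997961 to 169998240 (26.4 and 35.5). It was followed by a peak inside Lars2 (chromosome 9, 123461901 to 123462120, 36.4 and 71.0), one 7303 bp from Tra2a on chromosome 6 (27.3 and 60.4) and one inside Il31ra on chromosome 13 (25.7 and 45.9). A match of at least 90% identity over 80% of the peak existed elsewhere in the genome for 6 of the 10, including each of these 5 and a peak nearest Gm8797 on chromosome 3, against 3 of 200 randomly drawn distal peaks. The strongest with no such match lay 44 bp outside Srl, which encodes sarcalumenin, a calcium-binding protein of the sarcoplasmic reticulum (chromosome 16, 4541861 to 4542080, 19.3 and 44.2). Others with none were near Zfp395 (14.6 and 40.5) and near Txn2 (11.97 and 37.6).

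Recognition sequences of the insulator protein CTCF and of NFI factors had the highest ratios of centres to flanks in distal peaks. Those of NRF1 and REST followed. The ratio depends on how rare a consensus is in flanks, so it does not rank sequences of unlike length by importance. The central 150 bp held a CTCF consensus in 10.2% of the 61519 distal peaks, against 0.323% of windows 1000 bp to the side, a 31.6-fold difference. The NFI consensus was found in 3.82% against 0.352% (10.8-fold) and the NRF1 consensus in 0.0878% against 0.0203% (4.32-fold). The NRF1 ratio rests on 54 peaks with a match, and its rank against REST is unsettled. With a central window of 100 bp it was 3.73, against 4.99 for REST. The CTCF ratio was 48.0 with a central window of 100 bp and 24.5 with 200 bp. The REST consensus was at 0.579% against 0.159% (3.63-fold), the E-box listed under MYOD, which other bHLH factors also bind, at 20.6% against 7.58% (2.72-fold), and the ETS consensus at 0.356% against 0.132% (2.70-fold). More peaks held that E-box in the centre but not in the chosen flank (11664) than held CTCF so (6258). In the flank only, it was found in 3704 peaks, against 171 for CTCF. AP-1 (5.65% against 2.62%, 2.16-fold), HAND (5.47% against 2.86%, 1.92-fold), the steroid receptor element (1.84-fold), TEAD (6.05% against 3.61%, 1.67-fold), SPI1 (1.58-fold), NFY (1.12-fold) and SP-KLF (2.21-fold) were also higher. All 13 had adjusted p of 0.000139 or less in an exact binomial test of discordant peaks, two-sided, over 25 motifs. These p-values, like those of the motif tests below, describe the peaks of these 2 libraries, since peaks are not independent replicates. In the 8063 peaks whose windows held at most 10% repeat-masked bases, an alternative chosen after the data were seen, the calls for ETS (1.56-fold, adjusted p of 0.409), NFY (1.08-fold, 0.584), the steroid receptor element (1.35-fold, 0.113) and SPI1 (1.36-fold, 0.180) ended. The reversed consensus keeps base composition but not the order of bases, and so not CpG. It gave ratios of 1.11 for CTCF, 1.64 for NFI, 1.44 for MYOD, 0.987 for AP-1, 0.27 for HAND and 0.80 for TEAD. The fixed bases of the reversed MYOD and NFI sequences include CpG, unlike those of the consensus. Both were rare (0.241% and 0.00894% of flanks) and are weak controls, and the NFI ratio rests on 9 peaks. The reversed sequence of SP-KLF equals the consensus and controls nothing. That of HAND was itself far rarer in centres (0.611%) than in flanks (2.26%), for a reason not tested, and is a weak control too. In the 55235 distal peaks with no CTCF match, the HAND ratio was 1.91, in a test chosen after the data were seen.

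The GATA (0.791), TBX (0.692), FOX (0.587) and POU octamer (0.606) consensus were rarer in centres than in flanks, with adjusted p of 3.51e-13 or less, and their reversed sequences had ratios of 0.696, 1.21, 0.501 and 0.252. For GATA, FOX and the POU octamer the reversed sequence fell further than the consensus. Their lower shares are therefore not read as avoidance of these sites in particular. NKX2-5 (0.95), SRF (1.099), ESRR (0.957), RUNX (0.93), SOX (0.932) and HNF4 (1.13) did not pass the test, and HNF1 was found in 1 peak. NKX2-5, RUNX and SOX were lower with flanks at 500 bp (adjusted p of 0.00663, 0.0348 and 0.00766), at 2000 bp (0.00312, 0.00261 and 0.0353) and without replicate 1 (0.000919, 0.00217 and 0.0169). With the stronger peaks alone NKX2-5 (0.00142) and RUNX (0.00374) were lower, in the longer lists NKX2-5 was lower (0.0164) and HNF4 higher (0.0447), and without replicate 2 SRF was higher (0.0182). MEF2, the AT-rich site of the myocyte enhancer factors, was at 2.47% in centres and 2.44% in flanks (1.01-fold, exact binomial test, adjusted p = 0.716), with a ratio of 0.214 for its reversed sequence. By the same exact test, the MEF2 result depended on the peaks used: the ratio was 1.11 without replicate 2 (adjusted p = 8.03e-06), 0.823 without replicate 1 (1.88e-07) and 1.82 in the 8063 peaks with few repeat-masked bases (1.84e-05).

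**Figure D4:**
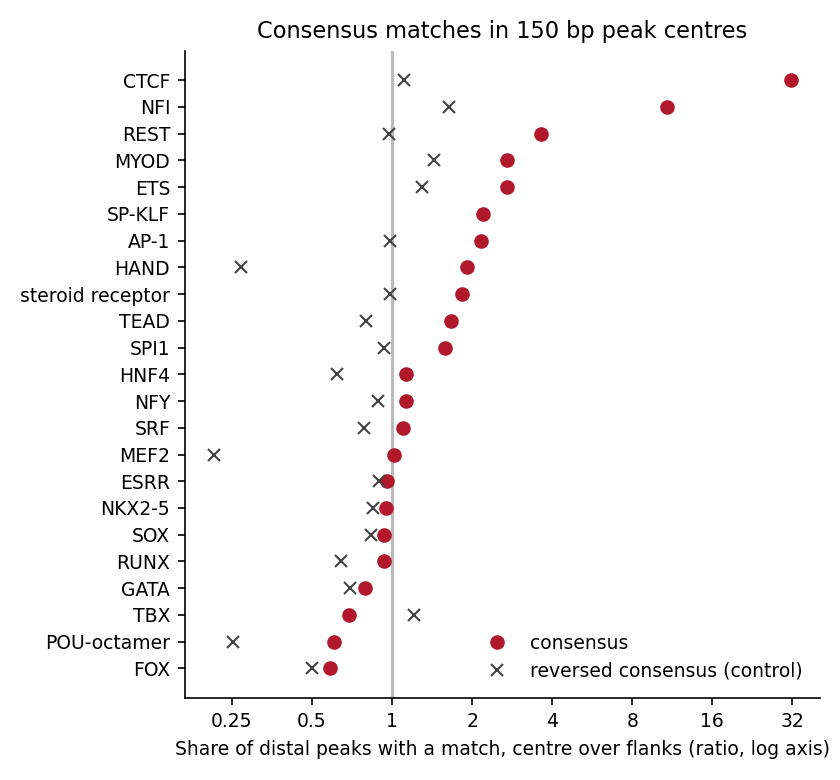
Ratio of the share of distal reproducible peaks with a consensus match in the central 150 bp to the share in windows 1000 bp to either side (log axis), for motifs matched in at least 100 peaks, with the reversed consensus as a control of base composition that does not keep CpG (crosses). CTCF (31.6-fold) and NFI (10.8-fold) stand furthest to the right, and the reversed sequence of MEF2 (0.214) furthest to the left.

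Footprints, short stretches inside accessible sites that the authors called as protected from cutting, covered most CTCF, NRF1 and NFI matches and few of some other motifs. There were 462394 in replicate 1 and 423331 in replicate 2, with median widths of 10 and 11 bp, and 70.4% and 71.9% lay in the same library's peaks. In reproducible peaks 66.6% of replicate 1 footprints overlapped a replicate 2 footprint, against 46.2% after they were moved at random within the peak, and 65.6% of replicate 2 footprints overlapped one of replicate 1, against 46.7%. With at least 50% of both footprints overlapping, the shares were 46.8% and 47.8%, against 15.0% and 15.7%. CTCF matches lay in footprints in 92.7% of 7233 cases in replicate 1 and 93.8% in replicate 2, against 23.3% and 20% for the reversed sequence. NRF1 (97.4% and 98.5%) and NFI (87.3% and 92.8%) matches were also mostly covered, and SP-KLF (73.1% and 74.5%), REST (60.0% and 63.0%) and ETS matches (56.6% and 57.8%) to a lower share. HAND (36.9% and 35.3%, reversed 10.5% and 15.3%) and MYOD E-box matches (31.8% and 32.7%, reversed 17.8% and 22.4%) lay above their reversed sequences. Both reversed sequences are weak controls, that of MYOD since it holds CpG and that of HAND since it was itself rare in peak centres. GATA (11.3% and 11.8%), AP-1 (16.4% and 15.1%), TEAD (18.5% and 18.9%), SPI1 (13.0% and 13.2%) and steroid receptor matches (8.62% and 10.3%) lay below the 19.8% and 22.1% of peak bases that footprints covered. Against their reversed sequences, TEAD (13.5% and 15.5%), SPI1 (9.87% and 12.2%) and steroid receptor matches (6.30% and 9.06%) lay higher in both libraries, AP-1 (13.3% and 16.5%) in replicate 1 only, and GATA (13.98% and 14.5%) lower in both. MEF2 matches were covered in 19.4% of 2596 cases in replicate 1 and 11.7% in replicate 2, against 15.7% and 16.3% for the reversed sequence. All matches were counted in reproducible peaks, promoter peaks included. Motifs were not matched on peak strength, so differences between their shares are not read as differences in binding.

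Chromosome 11 had the most peaks per length and chromosome X far fewer than any autosome in both hearts. Chromosome 11 held 69.3 and 69.5 peaks per Mb, the lowest autosome, chromosome 3, held 37.3 and 34.1, and the autosomal median was 48.1 and 46.0. Chromosome X held 16.8 and 16.04 peaks per Mb, 0.349 and 0.348 of that median. A reproducible promoter peak was found at 449 of 948 X-linked protein-coding genes (47.4%), against 53.7% for CpG-matched genes of other chromosomes (51.6% to 55.8%, the middle 95% of 2000 random lists). The median promoter value of X-linked genes with a peak was 3.22, against 6.93 for autosomal genes.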

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

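The test of male genes below was chosen after its result was seen, and the test of shared sequence before. Both animals were female, yet the lists held 21 peaks on chromosome Y in replicate 1 and 15 in replicate 2, which count among the peaks compared between the libraries. Male tissue in the sample is argued against by the male genes: 0 of the start sites of 8 genes of the male-specific part of Y (Ddx3y, Kdm5d, Uty, Eif2s3y, Zfy1, Zfy2, Usp9y and Sry) had a base at an FDR of 0.05 or less within 1000 bp in either library, while the 6 X copies tested, those of all but Sry, had one in both. Inside these male genes 6 listed stretches lay away from start sites, all in replicate 1 (3 in Usp9y and 1 each in Kdm5d, Uty and Zfy2), against 784 or more in each of those X copies in the same library. Sequence that Y shares with other chromosomes is a candidate source: 15 of the 21 and 8 of the 15 peaks, 63.9% together, matched another chromosome at 90% identity over 80% of their length, short of the 80% set for it and above the 30% set against it. With further copies on Y itself counted too, 19 of the 21 and 14 of the 15 had a match. In the last part of Y lay 8 and 10 of the peaks. Among them was the strongest of each library (90744561 to 90744820, value 2.00, and 90744601 to 90744820, 20.8). Which copy the reads came from stays open, and no biological explanation was tested.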

How the results depend on the processing

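The longer lists and the exclusion of repeat-masked windows were chosen after seeing the data. The cause of each change below was not tested unless the alternative itself sets it, as for stricter lists and wider windows. The stronger 50% of peaks left a mean of 56880.5 peaks and 12.7 Mb, and the longer lists gave 175048 and 34.7 Mb. The mean share of shared peaks (77.8%) was 66.7% with a reciprocal overlap of 0.5, 83.2% for the 50000 strongest and 74.4% in the longer lists. The correlation of strength was 0.870 for the 50000 strongest and 0.918 in the longer lists. The promoter share of peaks (25.7%) was 21.6% and 30.6% with windows of 500 and 2500 bp, 21.9% to 24.4% with 1 replicate left out, 37.3% for stronger peaks and 20.2% in the longer lists, always above the share at random. Promoter lists called higher (6) numbered 3 for stronger peaks and 10 without CpG matching. Those called lower (5) numbered 3 with a window of 2500 bp, 3 to 4 with 1 replicate left out and 2 in the longer lists. The leukocyte list turned to 1.08 times the random mean without replicate 2 (0.356 without replicate 1) and 1.31 times in the longer lists. Distal lists called higher (3) numbered 5 with 20 kb loci, 0 with 100 kb loci and 8 in the longer lists. Motifs called lower (4) numbered 7 with flanks at 500 bp, 7 at 2000 bp, 4 to 8 with 1 replicate left out and 12 in promoter peaks. Ratios that changed side of 1 were those for MEF2 without replicate 1 (0.823, against 1.11 without replicate 2) and, in promoter peaks, for MEF2 (0.393), TEAD (0.907), HAND (0.861), SRF (0.692), the steroid receptor element (0.804) and HNF4 (0.50). Values called under neither setting changed side as well. Promoter lists were cardiac transcription factors for stronger peaks (0.943) and in the longer lists (0.999), and Schwann cells and neurons at 2500 bp (1.05). Distal lists were macrophages at 20 kb (1.03) and for stronger peaks (1.17), liver in the longer lists (1.32), epithelia without replicate 1 (0.989, against 1.14), for stronger peaks (0.614) and in the longer lists (0.981), germ line at 100 kb (1.19), without replicate 2 (1.247, against 0.853), for stronger peaks (1.301) and in the longer lists (1.246), and the Hox clusters for stronger peaks (1.40). Motifs were MEF2 in the longer lists (0.950), SRF without replicate 1 (0.953, against 1.11) and without repeat-masked windows (0.732), ESRR with flanks at 2000 bp (1.004), without replicate 2 (1.08, against 0.929), in the longer lists (1.02) and without repeat-masked windows (1.62), RUNX without replicate 2 (1.03, against 0.905), and HNF4 with a 100 bp centre (0.982) and without repeat-masked windows (0.591). The share of shared footprints was 36.4% with an overlap of 50% of both and 66.1% inside reproducible peaks, against 51.8%. The X ratio (0.349) was 0.244 for stronger peaks and 0.372 in the longer lists. Of the 10 densest 50 kb windows, 6 overlapped a top window at 100 kb and 7 at 20 kb, where Bahcc1 ranked first. Over single lists and motifs, 17 of 140 promoter values were weaker and 10 stronger, 5 of 140 distal values weaker and 8 stronger, and 6 of 240 motif values weaker and 20 stronger, with 108, 116 and 197 unchanged. Depth is not stated, so weak sites absent from 1 library were not read as closed.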

Other observations

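The tests of rank change at motif sites and the exact test between sets of X-linked genes were chosen after their results, or closely related ones, were seen. The other tests of X-linked genes were set before. In promoter peaks the NRF1 consensus had the highest ratio of centres to flanks, where in distal peaks CTCF had, a difference that was not tested. In 26026 reproducible peaks within 1000 bp of any TSS, the NRF1 consensus was 17.4-fold, the ETS consensus 10.9-fold, the CTCF consensus 8.55-fold, the SP-KLF consensus 5.64-fold and the NFY consensus 2.66-fold as frequent in centres as in flanks, while MEF2 (0.393-fold) and GATA (0.343-fold) were rarer. NRF1 governs genes of mitochondrial function, and NFY and SP-KLF factors bind promoters of many widely expressed genes. Distal peaks with a CTCF match had a median value of 2.24, against 1.18 without one.

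Promoters on chromosome X had lower values than autosomal promoters with the same CpG content. Their median value was 0.55 of that of CpG-matched autosomal genes (middle 95% of random lists 0.494 to 0.614, 0.57 in replicate 1 and 0.527 in replicate 2), and no autosome set against the others lay outside 0.838 to 1.18, so CpG content does not account for it. Genes reported to escape X inactivation (Kdm6a, Kdm5c, Eif2s3x, Ddx3x, Pbdc1 and Utp14a) had a median promoter value of 12.3, against 3.96 for CpG-matched X-linked lists, at percentile 100 of 10000 of them, a direction that inactivation of 1 of the 2 X chromosomes in each cell predicts, so it may underlie part of the lower level. Their excess of 3.11-fold is larger than a second active copy alone would give, and they lay above CpG-matched autosomal lists too (8.08, percentile 92.7), so something else could raise them, such as activity in all cells: 8 inactivated genes used by nearly all cells (among them Pgk1, Hprt and G6pdx) had a median of 5.64, at percentile 87.5, which leaves that open, while the escape genes exceeded them by 1.18 on the log2 scale (exact permutation test, two-sided p = 0.00533).

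The 2 libraries, 1 per heart, differed in how they ranked peaks by motif. Among the same 61519 distal peaks ranked within each library, the 6284 with a CTCF match had a median percentile of 64.8 in replicate 1 and 77.4 in replicate 2, and 75.7% ranked higher in replicate 2. Their median change exceeded that of other peaks by 8.79 points, and REST matches moved by 14.2 and NFI matches by 6.28, whereas MEF2 (-9.45), steroid receptor (-7.61) and AP-1 (-5.40) matches moved the other way. Peak strength and GC content do not account for it: the CTCF change was 12.9 points within 10 bins of strength and 9.93 within 10 bins of GC content. Fewer heart muscle cells in replicate 2 could lower MEF2 sites, but distal peaks near contractile genes changed by 0.0407 points more than those near endothelial and fibroblast genes (95% bootstrap interval -4.28 to 3.22), too wide an interval to decide, and a difference in DNase digestion or fragment size, not analysed here, stays open too.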
